A study of Mus musculus with 139 samples.

How the data were processed

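RNA of mouse cells was measured in the tables described at the start of the results, and H3K27ac in 2 lists of peaks. Values in 6 tables are FPKM, fragments normalized to transcript length and library total, computed by the authors with TopHat2 2.0.11 and Cufflinks 2.0.2 on mm10, per the submitters' processing notes. Values in the nascent table are RPKM as deposited, which the authors made with Trim Galore, TopHat2 and bedtools on mm10 and dm6, and which were found to be reads per kilobase of the whole annotated gene span. Peaks were called by the authors with Bowtie2 2.2.6 and MACS2, and only their positions were deposited. Whether a spike-in factor was applied to any table, the strand and the versions of Trim Galore, MACS2 and bedtools are not given in the sources used here. The tables hold no spike-in transcripts. Each table lists 52885 genes, and 99.8% of their identifiers were matched to a symbol. Gene positions are given from the first base, and those in the tables started 1 base lower.

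Values were analysed as log2(value + 1), keeping genes of at least 1 in at least 2 libraries of the table. Group means were fitted with limma 3.58.1 (trend, moderated), with all groups of a table in the same model, in R 4.3.3 with data.table (version 1.17.8), and p-values were adjusted by Benjamini-Hochberg within each of 22 contrasts, with a threshold of 0.05. Changes are log2 differences of group means with the standard error of the fit, and group values are means with the SD over 2 libraries. Rescaling divided each library by the median ratio of its tested genes to their means over the table. The method was tested on simulated data, drawn around the mean of each gene with its SD between replicates, by adding known changes to 200 genes. These genes had mean values of about 5 or more. Noise was drawn separately for each gene, with no shift of whole libraries. Lists of 26 gene groups, written from textbook knowledge, were tested with camera at its preset correlation and again with a correlation estimated from the libraries, for lists with at least 5 measured members. The relative median of a list is its median log2 change minus that of all genes.

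The genes named follow a rule. It took Exosc2, the 6 largest rises and 6 largest falls per contrast among called genes whose libraries did not overlap and whose higher group had a mean of at least 5, and the 4 members of each list with the smallest p. Clones and short RNAs were passed over. For interactions overlap of libraries was not asked, and any group could reach the mean of 5. For the gradients it took the 6 largest shifts in each direction and the 2 largest of each list. The text prints part of the genes the rule gives, to keep it short. Some printed genes (mt-Co3, Hist1h2bh, Rps13, Rps19 and Rpl3) belong to groups whose reads were not separated from those of other loci. Gene classes, limma-voom and the genes called at 1 and 2 h in nascent RNA were added after the data were seen. Whole reads were recovered for the nascent table from the smallest step between values in each library.

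For the sucrose gradients a mean fraction number was computed per gene with summed values of at least 80 at both times, and lists were ranked against 10000 random lists matched in 20 bins of expression. Peaks were compared with bedtools 2.31.1, counting an overlap of at least 1 bp, with exact (Clopper-Pearson) 95% intervals, which cover counting error only. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The alternatives tried were a pseudocount of 0.1, no filter, rescaled libraries, replicate number as a block, no trend, and leaving out each library. For the gradients, peaks and comparisons across tables they were other minimum values, equal totals, fewer fractions and stricter overlap. Samples of other histone marks, RNA polymerase II, ATAC and Hi-C were not analysed here, since the questions asked concern RNA and active chromatin.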

Results

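The series profiled mouse embryonic stem cells (ESCs) of the line AID-FBEXOSC2. EXOSC2, a subunit of the RNA exosome that degrades and trims nuclear RNA, carries an auxin-inducible degron in this line, and 0.5 mM indole-3-acetic acid (IAA), an auxin, degrades it. The labels describe 139 samples, of which 70 libraries were used here. Total RNA depleted of ribosomal RNA was measured at 0, 4 and 20 h of IAA in ESCs and in fibroblasts derived from them with retinoic acid (iMEFs). Nascent RNA, labelled for 10 min with 5-ethynyluridine (EU), was measured at 0, 1, 2 and 4 h. Subcellular fractions at 0 and 4 h were the cytosol (cyto), the nucleoplasm (np), the insoluble chromatin fraction (chrRNP) and the whole-cell lysate (wcl). Polyadenylated RNA was measured at 0, 4 and 12 h in the nuclear pellet left after DNase I, urea, detergent and high salt (RNPmesh). It was also measured at 0, 4 and 20 h in ESCs without retinoic acid (RAD0) and after 24 h in 2 µM retinoic acid without LIF (RAD1). Each of these groups held 2 replicates, which may be technical, since the labels do not say how they were made. Sucrose fractions F2 to F9 of native nuclear lysate, at 0 and 12 h, had 1 library each, and H3K27ac was given as 2 lists of peaks, at 0 and 4 h. H3K4me3, H3K27me3, H3K9me3, RNA polymerase II, ATAC, Hi-C and the 20 h H3K27ac samples were not analysed here.

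The tables hold normalized values for 52885 genes, so the read depth per library is not given in the sources used here. Only the nascent values could be resolved into whole reads, and they implied 5355445 to 11306538 reads per library. Of these values 80.7% to 89.8% lay within 0.05 of a whole read, and 94.5% to 96.4% of the rounded counts were even, so 2 mates of a pair may have been counted apart. A simulated log2 change of 2 was recovered for at least 80% of seeded genes in every contrast except the nascent ones, where 61% to 75% were recovered. A change of 1 was recovered for 17% in RNPmesh, 25% for chrRNP minus cyto, 32% to 35% in nascent RNA and 52% to 90% in the others. Between 3 and 16 unchanged genes per contrast were called beside the seeded ones, 9 and 7 in nascent RNA at 1 and 2 h and 7 for chrRNP minus cyto. Only genes with mean values of about 5 or more were seeded, so recovery of lower genes was not measured. No whole library was shifted in the simulation, so false calls from such shifts were not covered. In RNPmesh 0 h replicate 2 the small RNA Snord49b took 42.2% of the summed value, in RNPmesh 4 h replicate 1 Mir6236 took 19.3%, and in ESC 4 h replicate 1 the transcript AY036118 took 15.2%. Gm42418 took 16.1% to 23.6% in the nascent libraries and Gm22357 14.6% to 18.8% in the chrRNP ones. The median gene of the 4 chrRNP libraries lay -0.78 to -0.36 (log2) from its mean across the table, which spans 4 kinds of fraction. No IAA-treated cells lacking the degron were used here, so each contrast with 0 h combines loss of EXOSC2 with any effect of IAA itself.

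Exosc2 (ENSMUSG00000039356.15, chromosome 2, 31670715 to 31681349; all positions are mm10) was measured as mRNA, while the degron acts on the protein, so its level does not measure the depletion. In ESCs it stood at 3.25 ± 0.711 FPKM (SD, n = 2) at 0 h and 2.41 ± 0.331 at 4 h, a log2 change of -0.31 ± 0.16 (SE, adjusted p = 0.165). It fell to 0.989 ± 0.0731 at 20 h (-1.08 ± 0.16, adjusted p = 0.000991). The median gene changed by -0.755 at 20 h, and after rescaling Exosc2 changed by -0.60 (adjusted p = 0.0218). It also fell in np (-0.65 ± 0.14, adjusted p = 0.00514) and in RNPmesh at 4 h (-1.40 ± 0.20, adjusted p = 0.00464) and 12 h (-1.70 ± 0.20, adjusted p = 0.000378). Without RNPmesh 4 h replicate 1 the RNPmesh call at 4 h ended (adjusted p = 0.0714). Exosc2 was not called in nascent RNA at 4 h (0.21 ± 0.22), chrRNP (0.00 ± 0.14), cyto (-0.04 ± 0.14) or wcl (-0.40 ± 0.14). It was not called either at 20 h in RAD0 (-0.45 ± 0.22), RAD1 (0.07 ± 0.22) or iMEFs (-0.34 ± 0.14).

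The first comparison asked how total RNA of ESCs differed after 4 h of IAA. Plk2, a kinase induced by the transcription factor p53 (ENSMUSG00000021701.8, chromosome 13, 110395046 to 110400844), went from 4.34 ± 0.665 to 31.3 ± 2.06 FPKM (2.60 ± 0.13, adjusted p = 0.000675). Btg2, an antiproliferative p53 target (ENSMUSG00000020423.6, chromosome 1, 134075170 to 134079120), went from 5.56 ± 1.29 to 37.5 ± 2.15 (2.56 ± 0.16, adjusted p = 0.00119). Mdm2, the ubiquitin ligase that degrades p53 (ENSMUSG00000020184.15, chromosome 10, 117688875 to 117710758), went from 19.5 ± 2.44 to 83.8 ± 9.91 (2.05 ± 0.14, adjusted p = 0.0018). Among noncoding transcripts Snhg20, a small nucleolar RNA host, rose by 2.29 ± 0.15, adjusted p = 0.00132, and Neat1, the scaffold of paraspeckles (ENSMUSG00000092274.2, chromosome 19, 5824708 to 5845478), by 1.36 ± 0.14, adjusted p = 0.00633. Prdm14, a repressor that guards naive pluripotency (ENSMUSG00000042414.7, chromosome 1, 13113457 to 13127163), fell from 4.35 ± 0.255 to 1.53 ± 0.0905 FPKM (-1.08 ± 0.13, adjusted p = 0.00953). Lefty1, a Nodal antagonist (-1.47 ± 0.18), Id3, an inhibitor of bHLH factors (ENSMUSG00000007872.3, chromosome 4, 136143497 to 136145392; -1.39 ± 0.15), the naive factor Klf2 (-1.06 ± 0.11) and Ccnt2, a cyclin of the elongation factor P-TEFb (-1.18 ± 0.13), fell too. With no filter on low values the calls of Lefty1 and Prdm14 ended (adjusted p = 0.054 and 0.0531), and without ESC 0 h replicate 1 that of Prdm14 ended (adjusted p = 0.065).

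Of 12461 genes tested in ESCs at 4 h, 557 genes were higher and 2639 lower, with a median change of -0.31 (661 and 435 after rescaling). With no filter 102 higher and 66 lower were called. Calls numbered 180 without 0 h replicate 1, 223 without 0 h replicate 2, 425 without 4 h replicate 1 and 5114 without 4 h replicate 2. Targets of p53 and cell-cycle inhibitors ranked higher (relative median 0.91, camera adjusted p = 1.17e-22, but adjusted p = 0.486 with an estimated correlation), with 15 of 28 members higher and 2 lower (18 and 2 adjusted over the list alone). Nuclear long noncoding RNAs and structured small RNAs ranked higher. Here 5 and 2 of 20 and 68 members were higher and 3 and 3 lower (7 and 0 and 4 and 2 adjusted over the list alone). Naive pluripotency, cell cycle, ribosome biogenesis, splicing factors and polymerase II elongation ranked lower. Here 15, 14, 17, 14 and 11 of 32, 36, 39, 41 and 34 members were lower and 1, 0, 0, 0 and 0 higher (19, 24, 31, 18 and 22 and 1, 0, 0, 0 and 0 adjusted over the list alone). Histones, whose paralogs' reads were not separated, had a median of -0.11 that turned to 0.20 on rescaling, with 3 of 61 members higher and 2 lower (2 and 0 adjusted over the list alone). None of the 9 camera calls held with an estimated correlation (adjusted p = 0.486 to 0.936 with an estimated correlation). On rescaling camera calls of structured small RNAs and splicing factors ended (adjusted p = 0.621 and 0.106). Grouped by annotated class, a choice made after the values were seen, 82 of 157 antisense transcripts rose and 3 fell (median 0.81; 89 and 3 adjusted over the list alone). Of 27 transcripts from bidirectional promoters 24 rose and 0 fell (median 1.14; 25 and 0 adjusted over the list alone). Among long intergenic RNAs 86 of 232 members rose and 17 fell (median 0.43; 94 and 22 adjusted over the list alone). Of processed transcripts 30 rose and 7 fell (median 0.31; 30 and 10 adjusted over the list alone). Provisional transcripts were split, since 60 of 278 members rose and 29 fell (median -0.04; 63 and 33 adjusted over the list alone), and 48 and 9 did after rescaling (median 0.14). Small RNAs did not rise as a whole: 3 of 118 small nucleolar RNAs rose and 9 fell (median -0.43; 2 and 8 adjusted over the list alone), 0 of 22 small nuclear RNAs rose and 2 fell (median -0.07; 0 and 2 adjusted over the list alone) and 2 of 31 other small RNAs rose and 4 fell (median -0.15; 1 and 4 adjusted over the list alone). Small nucleolar RNAs had a mean of -1.04, although camera ranked them higher (adjusted p = 0.0109, and adjusted p = 0.0789 with an estimated correlation). After rescaling that call ended and its direction turned (adjusted p = 0.66). Camera ranked small nuclear and other small RNAs higher too (adjusted p = 0.0499 and 0.00264). Those calls ended with an estimated correlation (adjusted p = 0.15 and 0.0789) and after rescaling (camera adjusted p = 0.316 for both). Of 10360 coding genes 225 rose and 2481 fell (225 and 2517 adjusted over the list alone), and 371 and 402 after rescaling. The antisense, bidirectional and long intergenic classes were also called with an estimated correlation (adjusted p = 0.0155, 0.0151 and 0.0313), while the calls of processed and provisional transcripts ended (adjusted p = 0.058 and 0.0919 with an estimated correlation).

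By 20 h Nr0b1, an orphan nuclear receptor of naive cells (ENSMUSG00000025056.4, chromosome X, 86191764 to 86195947), fell from 99.9 ± 4.13 to 7.12 ± 0.24 FPKM (-3.63 ± 0.11, adjusted p = 3.39e-05). Nanog (ENSMUSG00000012396.12, chromosome 6, 122707489 to 122714633) fell from 98.2 ± 2.77 to 10.4 ± 1.07 (-3.13 ± 0.14, adjusted p = 7.69e-05), and Tdgf1, a Nodal co-receptor, and the DNA methyltransferase Dnmt3b changed by -3.34 ± 0.16 and -2.18 ± 0.12. The G1/S cyclin Ccne1 (-2.87 ± 0.13), the folate enzyme Mthfd2 (-2.56 ± 0.12) and the nucleolar protein Nolc1 (-2.40 ± 0.14) fell. The histone gene Hist1h2bh (ENSMUSG00000114456.1, chromosome 13, 23541714 to 23543392) fell from 83.7 ± 0.396 to 13.9 ± 1.83 FPKM (-2.51 ± 0.14, adjusted p = 7.71e-05), and the exosome subunit Exosc7 changed by -1.63 ± 0.13. Plk2 reached 45.1 ± 2.55 FPKM (3.11 ± 0.13, adjusted p = 7.69e-05), Mdm2 117 ± 4.88 (2.53 ± 0.14, adjusted p = 7.71e-05), and Perp, a p53 target of cell junctions (ENSMUSG00000019851.8, chromosome 10, 18845020 to 18857073), 131 ± 9.62 from 24.1 ± 1.91 (2.39 ± 0.15, adjusted p = 8.31e-05). Krt18, a keratin of simple epithelia (ENSMUSG00000023043.6, chromosome 15, 102028216 to 102032026), rose from 8.52 ± 0.624 to 49.9 ± 0.552 FPKM (2.42 ± 0.12, adjusted p = 7.69e-05). The trophoblast factor Hand1 (2.19 ± 0.18), the protease inhibitor Serpine2 (3.02 ± 0.15), the YAP target Cyr61 (2.22 ± 0.14) and Neat1 (2.46 ± 0.14) rose.

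In all at 20 h 1180 genes were higher and 8451 lower, with a median change of -0.76 (2678 and 4582 after rescaling). The lists of p53 targets, immediate-early genes, senescence-associated secretory factors and epithelial and trophoblast markers ranked higher. Here 20, 14, 6 and 7 of 28, 24, 13 and 14 members were higher and 5, 5, 4 and 3 lower (20, 14, 7 and 7 and 5, 5, 4 and 3 adjusted over the list alone). Naive pluripotency, cell cycle, ribosome biogenesis, cytosolic ribosomal proteins, splicing factors, polymerase II elongation and replication-dependent histones ranked lower. Here 31, 35, 38, 69, 41, 30 and 53 of 32, 36, 39, 75, 41, 34 and 61 members were lower and 1, 0, 0, 0, 0, 0 and 2 higher (31, 35, 38, 69, 41, 30 and 53 and 1, 0, 0, 0, 0, 0 and 2 adjusted over the list alone). Reads of ribosomal protein genes were not separated from those of their pseudogenes. Nuclear long noncoding RNAs ranked higher with a median of 0.22 and a mean of -0.07, with 7 of 20 members higher and 7 lower (7 and 7 adjusted over the list alone). Structured small RNAs ranked higher too, with 5 of 68 members higher and 10 lower (5 and 7 adjusted over the list alone), while their median was -0.11, their mean 0.40 and their rescaled median 0.61. None of the 13 camera calls held with an estimated correlation (adjusted p = 0.157 to 0.797 with an estimated correlation). On rescaling the camera call of polymerase II elongation ended (adjusted p = 0.112).

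The change from 4 h to 20 h was tested directly. Krt18 (2.80 ± 0.12, adjusted p = 0.000161), Hand1 (2.40 ± 0.18), Plaur, the urokinase receptor (2.39 ± 0.11), and Perp (1.91 ± 0.15) rose over that interval. Nr0b1 (-3.29 ± 0.11, adjusted p = 9.4e-05), Ccne1 (-2.29 ± 0.13) and the replication clamp Pcna (-1.79 ± 0.16) fell. In all 980 genes were higher and 6054 lower, with a median change of -0.43 (2486 and 3835 after rescaling). Immediate-early genes, senescence-associated secretory factors, epithelial and trophoblast markers, p53 targets and structured small RNAs ranked higher. Here 15, 7, 8, 10 and 8 of 24, 13, 14, 28 and 68 members were higher and 3, 3, 2, 5 and 5 lower (15, 7, 8, 10 and 1 and 3, 3, 2, 5 and 0 adjusted over the list alone). Naive pluripotency, replication-dependent histones, cell cycle, cytosolic ribosomal proteins, ribosome biogenesis and splicing factors ranked lower. Here 29, 53, 35, 64, 38 and 34 of 32, 61, 36, 75, 39 and 41 members were lower and 0, 0, 0, 0, 0 and 0 higher (29, 54, 35, 67, 38 and 35 and 0, 0, 0, 0, 0 and 0 adjusted over the list alone). No call among these 11 held with an estimated correlation (adjusted p = 0.15 to 0.81 with an estimated correlation).

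**Figure D1:**
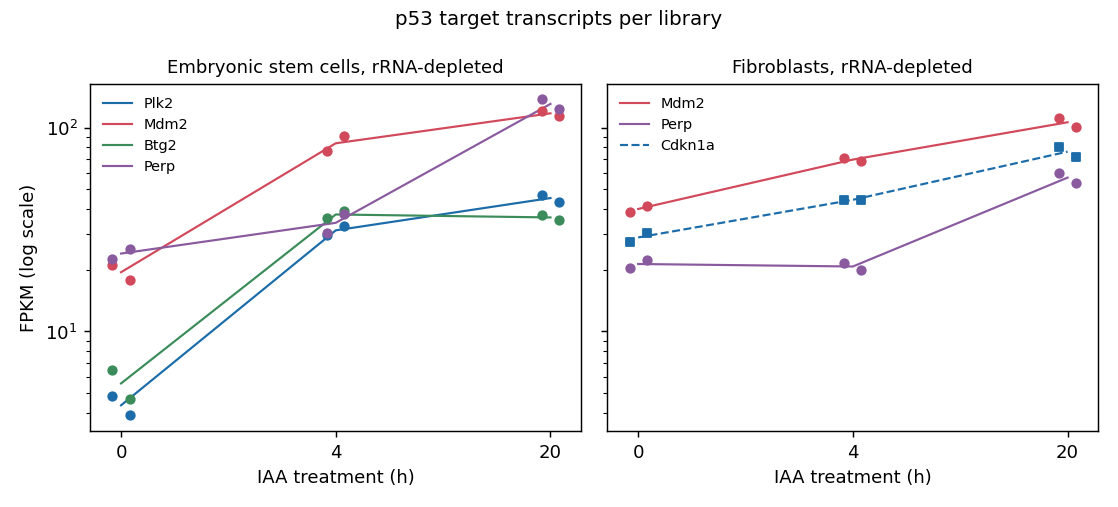
FPKM (log axis) of p53 target transcripts against hours of IAA, in ESCs (left) and iMEFs (right); points are single libraries (n = 2 per time) and lines join the means. Mdm2 rose from 19.5 to 117 FPKM in ESCs and from 39.9 to 106 in iMEFs by 20 h.

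The nascent RNA comparison asked which newly made transcripts changed within 4 h. At 4 h Mdm2 rose from 5.7 ± 0.507 to 68.7 ± 7.61 RPKM over the gene body (3.38 ± 0.13, adjusted p = 0.0048) and Plk2 from 0.688 ± 0.211 to 14.9 ± 1.34 (3.24 ± 0.29, adjusted p = 0.0238). Ccng1, a p53-induced cyclin (2.99 ± 0.34, adjusted p = 0.03), and Trp53inp1, a p53 cofactor (2.65 ± 0.15, adjusted p = 0.0132), rose. Btg2 was not called (2.51 ± 0.39, adjusted p = 0.05), but was after rescaling (adjusted p = 0.0477). The proneural factor Neurod1 (2.76 ± 0.23) and mt-Co3 (1.10 ± 0.11), whose reads were not separated from nuclear copies, also rose. Lin28a, a pluripotency RNA-binding protein (ENSMUSG00000050966.9, chromosome 4, 134003330 to 134018841), fell from 5.54 ± 0.17 to 2.01 ± 0.379 RPKM (-1.12 ± 0.12, adjusted p = 0.0297), as did Tdgf1 (-1.10 ± 0.17). Except for that of Mdm2, each of these calls ended when any 1 of the 4 libraries was left out (adjusted p from 0.0585 upward). With no filter those of Ccng1, mt-Co3 and Tdgf1 ended (adjusted p = 0.0577, 0.155 and 0.0781), and without the trend that of Tdgf1 (adjusted p = 0.0536).

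Of 8876 genes tested in nascent RNA at 4 h, limma called 139 higher and 30 lower (66 and 13 with no filter), with 1573 at an unadjusted p under 0.05. The p53 targets ranked higher (median 1.49), with 9 of 24 members higher and 0 lower (20 and 0 adjusted over the list alone). Mitochondrial transcripts ranked higher. Here 14 of 36 members were higher and 0 lower (18 and 0 adjusted over the list alone). The integrated stress response ranked lower. Here 2 of 19 members were lower and 0 higher (6 and 0 adjusted over the list alone). With an estimated correlation these 3 lists were still called (adjusted p = 0.0295, 0.0341 and 0.0356). Naive pluripotency, cytosolic ribosomal proteins and ribosome biogenesis ranked lower, with 2, 0 and 0 of 29, 80 and 39 members lower and 0, 0 and 1 higher (2, 0 and 0 and 0, 0 and 1 adjusted over the list alone), and histones higher, with 1 of 67 members higher and 0 lower (1 and 0 adjusted over the list alone), none of which held (adjusted p = 0.132 to 0.402 with an estimated correlation). At 2 h p53 targets already ranked higher (median 0.94, camera adjusted p = 1.71e-16, and adjusted p = 0.0348 with an estimated correlation), with 0 of 24 members higher and 0 lower (17 and 0 adjusted over the list alone). Mdm2 stood at 19.8 ± 0.46 RPKM at 2 h (1.63 ± 0.13, adjusted p = 0.0538), not called here but called with a pseudocount of 0.1, with no filter and without the trend (adjusted p = 0.0466, 0.0145 and 0.0303). Camera also called mitochondrial transcripts at 2 h, with 0 of 36 members higher and 0 lower (0 and 0 adjusted over the list alone). It called ribosomal proteins at 2 h, with 0 of 80 members lower and 0 higher (1 and 0 adjusted over the list alone). It called histones at 1 h, with 0 of 67 members lower and 0 higher (0 and 0 adjusted over the list alone). None of these calls held with an estimated correlation (adjusted p = 0.357, 0.374 and 0.665).

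Early counts were small: 4 genes higher and 0 lower at 1 h, and 1 higher and 0 lower at 2 h by limma-trend, with 487 and 719 at an unadjusted p under 0.05. With no filter 9 higher and 1 lower were called at 1 h and 29 and 4 at 2 h. The called genes, named after their values were seen, were the microRNA loci Mir6904, Mir664, Mir434 and Mir3078 at 1 h and the small nuclear RNA Gm22485 at 2 h, all listed at 0 at 0 h and resting on 4 to 16 implied reads per library, and on fewer pairs if mates were counted apart. A second tool, limma-voom on the recovered reads, chosen after seeing the data, called 1 higher and 3 lower at 1 h, 63 and 14 at 2 h and 369 and 271 at 4 h, of which 137 were shared with the 4 h calls. At 1 and 2 h it shared 0 calls with limma-trend. It called 9 of 24 p53 targets higher at 2 h and 17 at 4 h. Of 36 mitochondrial transcripts it called 12 higher and 0 lower at 2 h and 16 higher and 0 lower at 4 h. Leaving out 1 library moved each limma-trend count. At 1 h it was 6 without 0 h replicate 1, 2 without 0 h replicate 2 and 0 without 1 h replicate 2. At 2 h it was 0 without 0 h replicate 1, 4 without 0 h replicate 2, 3 without 2 h replicate 1 and 4 without 2 h replicate 2. At 4 h it was 3 without 0 h replicate 1, 4 without 0 h replicate 2, 7 without 4 h replicate 1 and 3 without 4 h replicate 2.

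Subcellular fractions were compared to ask how the RNA of each differed after 4 h. Values are normalized within each library, so they give shares within a fraction. A rise in a fraction therefore does not show where RNA accumulated in the cell. In chrRNP, Mdm2 (3.00 ± 0.17, adjusted p = 3.08e-06), Plk2 (2.87 ± 0.18), Nodal, a morphogen (1.31 ± 0.16), Zfc3h1, which links nuclear RNA to the exosome (0.78 ± 0.11, adjusted p = 0.00105), and Neat1, from 70.1 ± 2.93 to 464 ± 5.23 FPKM (2.71 ± 0.19, adjusted p = 1.14e-05), rose. Prdm14 fell (-0.59 ± 0.09, adjusted p = 0.00204). In all 1119 genes were higher and 122 lower, with a median change of 0.21 (1363 and 538 after rescaling). The count was 752 without chrRNP 0 h replicate 1, 5550 without chrRNP 0 h replicate 2 and 565 without chrRNP 4 h replicate 2. Nuclear long noncoding RNAs, p53 targets and replication-dependent histones ranked higher. Here 9, 20 and 4 of 20, 29 and 66 members were higher and 0, 0 and 0 lower (14, 22 and 4 and 1, 0 and 0 adjusted over the list alone). Formative pluripotency ranked lower, with 2 of 16 members lower and 0 higher (3 and 0 adjusted over the list alone), although its median was 0.05, its mean -0.02 and its rescaled median -0.03. None of the 4 held with an estimated correlation (adjusted p = 0.5 to 0.999 with an estimated correlation).

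In np, Plk2 (2.66 ± 0.18, adjusted p = 4.17e-06), Btg2 (2.49 ± 0.17), Mdm2 (2.29 ± 0.17) and Snhg4, a small nucleolar RNA host (ENSMUSG00000097769.7, chromosome 18, 35553371 to 35558316; 1.56 ± 0.17), rose. Prdm14 (-1.35 ± 0.09, adjusted p = 4.79e-06), Lefty1 (-1.14 ± 0.12) and Herpud1, a protein of endoplasmic reticulum stress (-1.41 ± 0.19), fell. In all 1046 genes were higher and 3287 lower, with a median change of -0.29 (1238 and 1621 after rescaling). Calls numbered 2187 without np 0 h replicate 1, 2118 without np 0 h replicate 2, 2063 without np 4 h replicate 1 and 2139 without np 4 h replicate 2. Integrated stress response, naive pluripotency, formative pluripotency, ribosome biogenesis, polymerase II elongation, cell cycle and splicing factors ranked lower. Here 13, 13, 7, 11, 15, 8 and 7 of 22, 32, 16, 39, 34, 36 and 41 members were lower and 0, 1, 0, 0, 0, 0 and 0 higher (14, 14, 8, 13, 18, 5 and 7 and 0, 1, 0, 0, 1, 0 and 0 adjusted over the list alone). The lists of p53 targets, nuclear long noncoding RNAs, histones and structured small RNAs ranked higher. Here 17, 7, 3 and 6 of 29, 20, 66 and 97 members were higher and 2, 4, 1 and 3 lower (17, 7, 2 and 2 and 2, 5, 0 and 0 adjusted over the list alone). Noncoding RNAs had a median of -0.03, a mean of 0.28 and a rescaled median of 0.16, histones a median of -0.08 and a rescaled one of 0.13, and structured small RNAs a median of 0 and a mean of 0.73. None of these 11 held with an estimated correlation (adjusted p = 0.611 to 0.838 with an estimated correlation). On rescaling the camera call of splicing factors ended (adjusted p = 0.0755).

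In cyto the small nucleolar RNA host Snhg4 went from 8.32 ± 1.73 to 80.6 ± 4.52 FPKM (3.14 ± 0.17, adjusted p = 3.82e-06) and Snhg3 changed by 2.18 ± 0.20. Plk2 (2.84 ± 0.18), Mdm2 (2.22 ± 0.17) and the p21 gene Cdkn1a (1.65 ± 0.13) rose, and the splicing kinase Clk4 (-0.89 ± 0.13, adjusted p = 0.00169) and Prdm14 (-0.68 ± 0.09) fell. In all 709 genes were higher and 198 lower (652 and 359 after rescaling). The count was 591 without cyto 0 h replicate 1, 587 without cyto 0 h replicate 2 and 470 without cyto 4 h replicate 2. Small nucleolar RNA hosts, nuclear long noncoding RNAs, p53 targets and replication-dependent histones ranked higher. Here 6, 7, 16 and 3 of 18, 20, 29 and 66 members were higher and 1, 0, 0 and 0 lower (7, 10, 19 and 3 and 1, 0, 0 and 0 adjusted over the list alone). Naive pluripotency, formative pluripotency, integrated stress response and interferon response ranked lower. Here 2, 4, 3 and 0 of 32, 16, 22 and 10 members were lower and 1, 0, 0 and 0 higher (3, 5, 5 and 1 and 1, 0, 1 and 0 adjusted over the list alone). None of these 8 held with an estimated correlation (adjusted p = 0.193 to 0.997 with an estimated correlation).

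In wcl, Snhg9, another host (3.08 ± 0.44, adjusted p = 0.00117), Plk2 (2.60 ± 0.18), Btg2 (2.36 ± 0.17) and Cdkn1a (1.58 ± 0.13) rose, and Ccne2, an S-phase cyclin (-1.22 ± 0.14, adjusted p = 0.000373), Prdm14 (-1.16 ± 0.09) and Herpud1 (-1.36 ± 0.19) fell. In all 808 genes were higher and 1899 lower, with a median change of -0.23 (946 and 691 after rescaling). Calls numbered 1194 without wcl 0 h replicate 1, 1134 without wcl 0 h replicate 2, 1140 without wcl 4 h replicate 1 and 1246 without wcl 4 h replicate 2. Small nucleolar RNA hosts, nuclear long noncoding RNAs, p53 targets, replication-dependent histones and structured small RNAs ranked higher. Here 5, 8, 17, 3 and 0 of 18, 20, 29, 66 and 97 members were higher and 2, 1, 1, 0 and 2 lower (5, 8, 18, 1 and 0 and 2, 3, 3, 0 and 1 adjusted over the list alone). Histones had a median of -0.02, a mean of 0.07 and a rescaled median of 0.20, and structured small RNAs a median of 0.09 and a mean of -0.06. Naive pluripotency, formative pluripotency, integrated stress response and polymerase II elongation ranked lower. Here 9, 6, 6 and 8 of 32, 16, 22 and 34 members were lower and 1, 0, 0 and 0 higher (12, 6, 9 and 9 and 1, 0, 0 and 0 adjusted over the list alone). None of these 9 held with an estimated correlation (adjusted p = 0.342 to 0.997 with an estimated correlation). On rescaling camera calls of structured small RNAs and polymerase II elongation ended (adjusted p = 0.108 and 0.095).

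Whether the 4 h change differed between chrRNP and cyto was tested as an interaction. Each change is of shares within its own fraction, so a difference does not show that RNA moved between fractions. Snhg4 went from 38 ± 3.51 to 94.7 ± 8.58 FPKM in chrRNP, a smaller change than in cyto (-1.84 ± 0.24, adjusted p = 0.0146). Rbm3, a cold-inducible RNA-binding protein (ENSMUSG00000031167.16, chromosome X, 8138978 to 8145880; 1.47 ± 0.21, adjusted p = 0.0262), and Wdr35, a ciliary transport protein (1.30 ± 0.19, adjusted p = 0.0262), had higher changes in chrRNP. Neat1 differed by 1.58 ± 0.27, adjusted p = 0.0629, and was called after rescaling (1.48, adjusted p = 0.0384), with no filter (adjusted p = 0.0356) and without the trend (adjusted p = 0.0396). In all 13 genes had a higher and 6 a lower difference (45 and 12 after rescaling, 37 and 37 with no filter), with 1233 at an unadjusted p under 0.05. The count was 2690 without chrRNP 0 h replicate 2, 8 without chrRNP 4 h replicate 1 and 12 without chrRNP 4 h replicate 2. The calls of Snhg4, Rbm3 and Wdr35 each ended without cyto 0 h replicate 2, chrRNP 4 h replicate 1 or cyto 4 h replicate 1 (highest adjusted p = 0.0797, 0.12 and 0.133). Those of Rbm3 and Wdr35 also ended without cyto 0 h replicate 1 or chrRNP 4 h replicate 2, and those of Snhg4 and Rbm3 without cyto 4 h replicate 2. Host transcripts and structured small RNAs ranked lower, with 1 and 0 of 18 and 97 members lower and 0 and 1 higher (1 and 1 and 0 and 1 adjusted over the list alone), and cell cycle genes higher, with 0 of 36 members higher and 0 lower (0 and 0 adjusted over the list alone). Structured small RNAs had a median of 0.11 and a mean of -0.27. None of the 3 held (adjusted p = 0.927 or more with an estimated correlation).

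The RNPmesh comparison asked how polyadenylated RNA in the insoluble nuclear pellet changed. Prrg4, a transmembrane Gla protein (ENSMUSG00000027171.10, chromosome 2, 104830741 to 104849876), rose from 0.854 ± 0.00778 to 27.8 ± 1.72 FPKM at 4 h (3.96 ± 0.19, adjusted p = 8.13e-05) and 80.6 ± 6.23 at 12 h (5.46 ± 0.19, adjusted p = 6.08e-06). Plk2 rose by 2.42 ± 0.19 and 3.62 ± 0.19, and at 12 h Serpine2 (4.09 ± 0.35), Egr1, an immediate-early factor (1.85 ± 0.22), and the polymerase II subunit Polr2a (2.23 ± 0.29) rose. Chac1, an ATF4-induced glutathione enzyme (ENSMUSG00000027313.3, chromosome 2, 119351229 to 119354381), fell at 4 h (-2.57 ± 0.20, adjusted p = 0.000854) and 12 h (-3.06 ± 0.20, adjusted p = 6.11e-05). The host transcript Snhg5 (ENSMUSG00000097195.9, chromosome 9, 88521050 to 88522929) went from 167 ± 5.59 to 27.7 ± 1.82 and 19 ± 1.13 FPKM (-2.55 ± 0.20, adjusted p = 0.000854 and -3.07 ± 0.20, adjusted p = 6.11e-05). Klf2 (-1.78 ± 0.24) and Rps13 (-1.53 ± 0.19) fell at 4 h, and Foxd3 (-2.60 ± 0.29), Rps19 (-2.16 ± 0.24) and the imprinted noncoding RNA Meg3 (-2.98 ± 0.36) at 12 h. Without 4 h replicate 1 the calls of Rps13 and Klf2 ended (adjusted p = 0.0569 and 0.0674).

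At 4 h in RNPmesh 699 genes were higher and 2426 lower, with a median change of -0.20 (1248 and 1443 after rescaling). With no filter 298 higher and 901 lower were called. The count was 1613 without 0 h replicate 2, 55 without 4 h replicate 1 and 706 without 4 h replicate 2. At 12 h 2078 genes were higher and 4024 lower, with a median change of -0.23 (2930 and 3233 after rescaling). Cytosolic ribosomal proteins, small nucleolar RNA hosts and integrated stress response ranked lower at 4 h, with 33, 9 and 11 of 68, 16 and 23 members lower and 0, 1 and 0 higher (42, 10 and 14 and 0, 1 and 0 adjusted over the list alone), and at 12 h, with 56, 10 and 15 of 68, 16 and 23 members lower and 0, 0 and 0 higher (61, 10 and 15 and 0, 0 and 0 adjusted over the list alone). The lists of p53 targets, histones and fibroblast markers ranked higher at 4 h. Here 16, 4 and 0 of 28, 22 and 11 members were higher and 2, 1 and 0 lower (19, 3 and 0 and 2, 1 and 0 adjusted over the list alone). At 12 h p53 targets ranked higher. Here 21 of 28 members were higher and 4 lower (21 and 4 adjusted over the list alone). None held (adjusted p = 0.554 to 0.781 at 4 h and 0.55 to 0.777 at 12 h with an estimated correlation). On rescaling camera calls of replication-dependent histones and fibroblast markers ended (adjusted p = 0.107 and 0.0536).

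In the retinoic acid series the effect of IAA was first asked in cells kept without retinoic acid (RAD0). At 4 h Plk2 (2.92 ± 0.05, adjusted p = 3.35e-08), Btg2 (2.49 ± 0.06), Mdm2 (2.28 ± 0.05) and Snhg20 (2.04 ± 0.14) rose, and Chac1 (-2.45 ± 0.13, adjusted p = 1.45e-05), Id3 (-1.26 ± 0.11) and Nanog (-0.66 ± 0.05) fell. At 20 h Plk2 (4.11 ± 0.05, adjusted p = 1.8e-09), Perp (3.25 ± 0.04, adjusted p = 1.47e-09), Krt19, an epithelial keratin (2.08 ± 0.19), Jun (2.22 ± 0.14) and Neat1, from 139 ± 0.0707 to 1406 ± 46 FPKM (3.33 ± 0.06, adjusted p = 9.75e-09), were higher. Nanog fell from 293 ± 3.68 to 78.4 ± 1.02 FPKM (-1.89 ± 0.05, adjusted p = 6.17e-08), and Ccne1 (-1.69 ± 0.06), the serine enzyme Psat1 (-2.45 ± 0.05) and Rpl3 (-1.79 ± 0.12) fell by 20 h. At 4 h 811 genes were higher and 2087 lower, with a median change of -0.11 (879 and 878 after rescaling). Calls numbered 1727 without 0 h replicate 1, 1250 without 0 h replicate 2, 1477 without 4 h replicate 1 and 1334 without 4 h replicate 2. At 20 h 2842 genes were higher and 5081 lower, with a median change of -0.13 (3440 and 4138 after rescaling).

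As sets in RAD0 at 4 h, p53 targets, nuclear long noncoding RNAs and small nucleolar RNA hosts ranked higher. Here 21, 12 and 6 of 30, 22 and 19 members were higher and 1, 1 and 2 lower (21, 13 and 8 and 2, 1 and 2 adjusted over the list alone). Naive pluripotency and the integrated stress response ranked lower. Here 19 and 17 of 32 and 23 members were lower and 1 and 0 higher (22 and 19 and 1 and 0 adjusted over the list alone). These 5 were also called with an estimated correlation (adjusted p = 0.000532, 0.0476, 0.0323, 0.0323 and 0.0177). Cell cycle, ribosome biogenesis, polymerase II elongation and Polycomb proteins ranked lower, with 15, 16, 12 and 8 of 36, 39, 34 and 20 members lower and 0, 0, 1 and 0 higher (18, 24, 15 and 13 and 0, 0, 1 and 0 adjusted over the list alone), and histones higher, with 2 of 50 members higher and 1 lower (2 and 1 adjusted over the list alone), a median of 0 and a mean of 0.07. These did not hold (adjusted p = 0.0743 to 0.166 with an estimated correlation). On rescaling camera calls of replication-dependent histones, cell cycle and polymerase II elongation ended (adjusted p = 0.206, 0.104 and 0.104). At 20 h p53 targets, replication-dependent histones and immediate-early genes ranked higher, with 24, 21 and 11 of 30, 50 and 24 members higher and 3, 1 and 5 lower (25, 18 and 11 and 3, 1 and 5 adjusted over the list alone), and the integrated stress response and cell cycle lower, with 18 and 29 of 23 and 36 members lower and 0 and 1 higher (18 and 29 and 0 and 1 adjusted over the list alone). With an estimated correlation their adjusted p was 0.00215, 0.00912, 0.0471, 0.0204 and 0.0471. Histones ranked lower at 20 h in ESC total RNA depleted of ribosomal RNA. The RAD0 and RAD1 libraries hold polyadenylated RNA, a different pool, so their histone results cannot be compared directly with that one. Epithelial and trophoblast markers, nuclear long noncoding RNAs and small nucleolar RNA hosts ranked higher, with 10, 13 and 9 of 14, 22 and 19 members higher and 3, 4 and 5 lower (10, 13 and 9 and 3, 4 and 5 adjusted over the list alone), and naive pluripotency, heat shock, cytosolic ribosomal proteins and ribosome biogenesis lower, with 25, 11, 58 and 36 of 32, 15, 80 and 39 members lower and 5, 0, 1 and 2 higher (25, 12, 58 and 37 and 5, 0, 2 and 2 adjusted over the list alone). None of these 7 held (adjusted p = 0.0505 to 0.139 with an estimated correlation). At 20 h rescaling also ended the call of hosts (adjusted p = 0.05).

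The response to retinoic acid without IAA, RAD1 against RAD0, gave the background for the next question. RAD1 cells were also kept without LIF. What is called the response to retinoic acid therefore includes any effect of lacking LIF. Cyp26a1, the enzyme that clears retinoic acid (ENSMUSG00000024987.5, chromosome 19, 37697808 to 37701528), rose from 0.793 ± 0.168 to 267 ± 6.22 FPKM (7.22 ± 0.21, adjusted p = 1.13e-07), and Hoxb1 (5.83 ± 0.21), Hoxa5 (5.62 ± 0.20) and the endoderm factor Gata6 (3.08 ± 0.15) rose. Tdgf1 (-3.38 ± 0.04, adjusted p = 1.45e-09), the naive factor Esrrb (-3.22 ± 0.06) and Fgf4 (-2.44 ± 0.05) fell. In all 4262 genes were higher and 2931 lower (3589 and 3621 after rescaling). The retinoic acid list ranked higher, with 27 of 30 members higher and 1 lower (27 and 1 adjusted over the list alone), and naive pluripotency and ribosome biogenesis lower, with 27 and 37 of 32 and 39 members lower and 4 and 0 higher (27 and 37 and 4 and 0 adjusted over the list alone). All 3 held (adjusted p = 0.0239, 0.0128 and 0.0239 with an estimated correlation). Mesoderm and endoderm and p53 targets ranked higher, with 8 and 18 of 15 and 30 members higher and 3 and 6 lower (8 and 18 and 3 and 6 adjusted over the list alone), and RNA exosome and cofactors, cell cycle, heat shock, cytosolic ribosomal proteins and mitochondrial transcripts lower, with 15, 19, 7, 17 and 4 of 28, 36, 15, 80 and 13 members lower and 1, 3, 2, 1 and 0 higher (15, 19, 8, 11 and 4 and 1, 4, 2, 1 and 0 adjusted over the list alone). None of these 7 held (adjusted p = 0.0557 to 0.322 with an estimated correlation).

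The effect of IAA was then asked under retinoic acid (RAD1). Cyp26b1, a retinoic acid hydroxylase (ENSMUSG00000063415.12, chromosome 6, 84571414 to 84593908), went from 31.3 ± 1.6 FPKM without IAA to 1.35 ± 0.421 at 4 h (-3.79 ± 0.17, adjusted p = 7.23e-07) and 1.17 ± 0.246 at 20 h (-3.90 ± 0.17, adjusted p = 2.66e-07). Hoxb1 (ENSMUSG00000018973.2, chromosome 11, 96365752 to 96368256) fell from 73.8 ± 0.806 to 4.01 ± 0.836 at 20 h (-3.91 ± 0.21, adjusted p = 1.13e-06), and Hoxb5 (ENSMUSG00000038700.4, chromosome 11, 96303512 to 96306120) from 41.9 ± 1.68 to 11.9 ± 1.61 at 4 h (-1.73 ± 0.14, adjusted p = 2.22e-05). The homeobox gene Gbx2 (-2.25 ± 0.08) and the replication helicase subunit Mcm3 (-1.55 ± 0.04) fell at 20 h. Perp rose from 18.7 ± 0.233 to 264 ± 5.59 and 575 ± 0.354 FPKM (3.75 ± 0.04, adjusted p = 4.32e-10 and 4.87 ± 0.04, adjusted p = 4.68e-11). Plk2 rose by 4.13 ± 0.05 and 4.60 ± 0.05, and at 20 h the p53 target Sfn (4.96 ± 0.10) and the claudin Cldn4 (4.47 ± 0.12) rose. At 4 h 2787 genes were higher and 5046 lower, with a median change of -0.14 (3365 and 3999 after rescaling), and at 20 h 3561 genes were higher and 5215 lower, with a median change of -0.11 (4044 and 4475 after rescaling).

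The retinoic acid list ranked lower under RAD1, with 25 of 30 members lower and 3 higher (25 and 3 adjusted over the list alone) at 4 h and 27 of 30 members lower and 1 higher (27 and 1 adjusted over the list alone) at 20 h (adjusted p = 0.155 and 0.0748 with an estimated correlation). The lists of p53 targets, replication-dependent histones and immediate-early genes ranked higher, with 24, 21 and 14 of 30, 50 and 24 members higher and 3, 2 and 5 lower (24, 21 and 15 and 3, 2 and 5 adjusted over the list alone) at 4 h and 24, 15 and 19 of 30, 50 and 24 members higher and 3, 1 and 2 lower (24, 12 and 19 and 3, 0 and 3 adjusted over the list alone) at 20 h. Cell cycle ranked lower, with 33 of 36 members lower and 1 higher (33 and 1 adjusted over the list alone) at 4 h and 35 of 36 members lower and 0 higher (35 and 0 adjusted over the list alone) at 20 h. These 4 held (highest adjusted p = 0.021 at 4 h and 0.0277 at 20 h with an estimated correlation). The integrated stress response ranked lower, with 17 of 23 members lower and 1 higher (17 and 1 adjusted over the list alone) at 4 h and 16 of 23 members lower and 4 higher (16 and 4 adjusted over the list alone) at 20 h, and held at 4 h (adjusted p = 0.0311 and 0.0964 with an estimated correlation). At 4 h nuclear long noncoding RNAs and neuroectoderm ranked higher, with 12 and 7 of 22 and 12 members higher and 1 and 4 lower (14 and 7 and 1 and 4 adjusted over the list alone), and heat shock, mesoderm and endoderm and cytosolic ribosomal proteins lower, with 9, 11 and 53 of 15, 15 and 80 members lower and 1, 1 and 3 higher (9, 11 and 55 and 1, 1 and 3 adjusted over the list alone). At 20 h epithelial and trophoblast markers and nuclear long noncoding RNAs ranked higher, with 11 and 13 of 14 and 22 members higher and 2 and 3 lower (11 and 13 and 2 and 3 adjusted over the list alone), and cytosolic ribosomal proteins and ribosome biogenesis lower, with 59 and 24 of 80 and 39 members lower and 1 and 4 higher (60 and 24 and 1 and 4 adjusted over the list alone). These did not hold (adjusted p = 0.11 to 0.258 at 4 h and 0.0748 to 0.365 at 20 h with an estimated correlation). On rescaling the camera call of neuroectoderm ended (adjusted p = 0.0813). At 20 h rescaling ended that of ribosome biogenesis (adjusted p = 0.118).

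Whether the response to retinoic acid differed with IAA was tested as an interaction, the change with IAA minus that without. Higher and lower are meant with the sign, so a higher response can be a smaller fall. At 20 h the response of Cyp26b1 (-4.11 ± 0.23, adjusted p = 1.99e-05), Hoxb6 (-4.09 ± 0.26), Hoxb1 (-3.76 ± 0.30), Gata6 (-2.30 ± 0.22) and the proliferation marker Mki67 (-1.38 ± 0.07, adjusted p = 1.68e-05) was lower. Esrrb (1.38 ± 0.09, adjusted p = 3.38e-05), Sfn (3.68 ± 0.14, adjusted p = 4.76e-06) and the stress factor Atf3 (2.70 ± 0.19) had positive interactions. For Esrrb this was a smaller fall with retinoic acid, from 128.9 to 35.3 FPKM at 20 h of IAA and from 175.5 to 17.9 without IAA. Sfn fell with retinoic acid from 23.3 to 2.57 FPKM without IAA and rose from 57.9 to 109.9 at 20 h. At 4 h Cyp26b1 (-4.03 ± 0.23, adjusted p = 2.06e-05) and Hoxb5 (-1.60 ± 0.20) had lower and Perp (3.07 ± 0.05, adjusted p = 4.47e-08), the p53 target Pmaip1 (2.54 ± 0.12) and Neat1 (2.70 ± 0.08) higher ones. With a pseudocount of 0.1 the calls of Hoxb1 at 20 h and Hoxb5 at 4 h ended (-3.42, adjusted p = 0.0704, and -1.21, adjusted p = 0.289). In all 2146 genes had a higher and 1795 a lower interaction at 20 h, and 1962 and 2233 at 4 h.

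The retinoic acid list had lower interactions at 20 h, with 25 of 30 members lower and 1 higher (25 and 1 adjusted over the list alone) and a median of -1.34 (adjusted p = 0.0431 with an estimated correlation). At 4 h it had 20 of 30 members lower and 0 higher (22 and 3 adjusted over the list alone) (adjusted p = 0.0939 with an estimated correlation). Cell cycle was lower, with 30 of 36 members lower and 1 higher (32 and 1 adjusted over the list alone) at 20 h and 27 of 36 members lower and 1 higher (29 and 1 adjusted over the list alone) at 4 h, and immediate-early genes higher, with 11 of 24 members higher and 1 lower (12 and 2 adjusted over the list alone) and 16 of 24 members higher and 1 lower (18 and 1 adjusted over the list alone). These held at both times (adjusted p = 0.0222, 0.014, 0.0436 and 0.0116 with an estimated correlation). At 4 h p53 targets, naive pluripotency and replication-dependent histones had higher interactions, with 19, 18 and 7 of 30, 32 and 50 members higher and 4, 2 and 1 lower (20, 20 and 6 and 4, 2 and 1 adjusted over the list alone), and held (adjusted p = 0.0116, 0.029 and 0.029 with an estimated correlation). By camera alone, naive pluripotency, p53 targets, neuroectoderm, ribosome biogenesis and epithelial and trophoblast markers were higher at 20 h, with 17, 14, 5, 20 and 6 of 32, 30, 12, 39 and 14 members higher and 4, 5, 2, 1 and 1 lower (21, 15, 5, 24 and 7 and 5, 5, 2, 1 and 1 adjusted over the list alone) (adjusted p = 0.0777 to 0.198 with an estimated correlation). At 4 h neuroectoderm and epithelial and trophoblast markers were higher, with 7 and 5 of 12 and 14 members higher and 2 and 2 lower (7 and 5 and 3 and 2 adjusted over the list alone), and heat shock, cytosolic ribosomal proteins and mesoderm and endoderm lower, with 8, 31 and 5 of 15, 80 and 15 members lower and 0, 1 and 1 higher (8, 40 and 6 and 2, 1 and 2 adjusted over the list alone) (adjusted p = 0.137 to 0.337 with an estimated correlation).

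**Figure D2:**
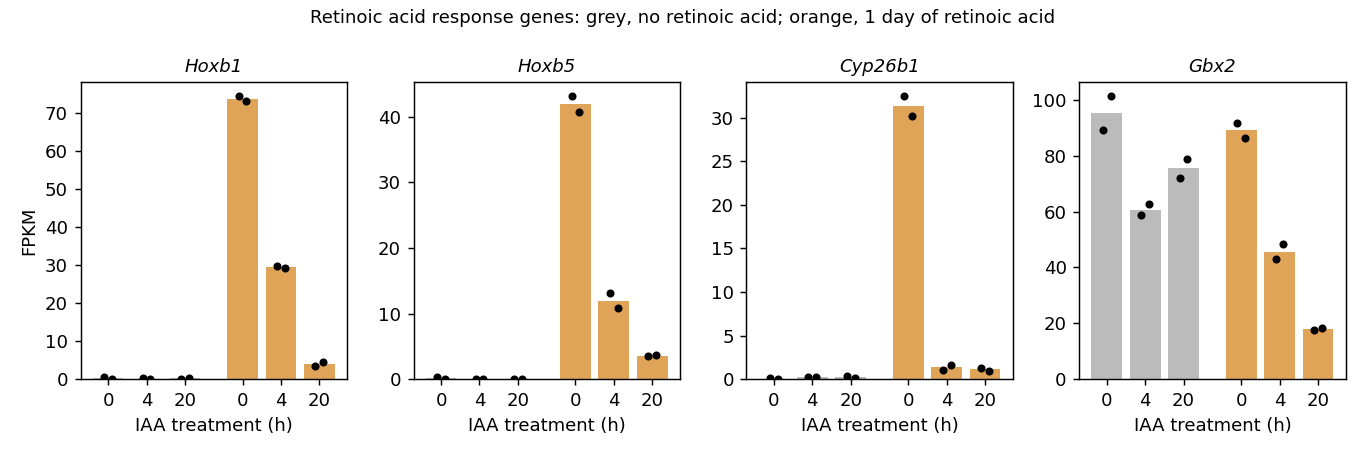
FPKM of Hoxb1, Hoxb5, Cyp26b1 and Gbx2 (linear axes from 0) against hours of IAA, without retinoic acid (grey) and after 1 day of it (orange); bars are means and points single libraries (n = 2 per group). With retinoic acid Hoxb1 stood at 73.8 FPKM without IAA and 4.01 at 20 h.

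Whether fibroblasts responded was asked in iMEFs. At 4 h Snhg20 (1.62 ± 0.14, adjusted p = 0.00477), Snhg4 (1.77 ± 0.17, adjusted p = 0.00673), Neat1 (0.95 ± 0.13) and Mdm2 (0.79 ± 0.10, adjusted p = 0.0185) rose, and Cdkn1a changed by 0.60 ± 0.10, adjusted p = 0.0542, or by 0.75 after rescaling (adjusted p = 0.00523). At 20 h Mdm2 rose from 39.9 ± 1.93 to 106 ± 7.28 FPKM (1.39 ± 0.10, adjusted p = 0.000542), with Perp (1.36 ± 0.10) and Cdkn1a (1.37 ± 0.10). Mki67 (-1.86 ± 0.09, adjusted p = 0.000364), the cyclin Ccna2 (-1.94 ± 0.10), Hist1h2bh, from 22.4 ± 0.53 to 3.72 ± 0.65 FPKM (-2.31 ± 0.12, adjusted p = 0.000364), Exosc8 (-1.21 ± 0.16) and the fibroblast gene Pdgfra (-0.67 ± 0.10) fell at 20 h. The 4 h calls of Mdm2 and Neat1 ended without any 1 of the 4 libraries (adjusted p up to 0.137 and 0.102). With no filter the 4 h calls of Mdm2, Neat1 and Snhg4 ended (adjusted p = 0.0512, 0.0814 and 0.0623). At 4 h 186 genes were higher and 26 lower, with a median change of -0.17 (293 and 39 after rescaling), with 3428 at an unadjusted p under 0.05, and at 20 h 677 genes were higher and 2880 lower, with a median change of -0.19 (1465 and 1965 after rescaling). With no filter 83 higher and 16 lower were called at 4 h and 541 and 1658 at 20 h. The 4 h count was 129 without 0 h replicate 1, 140 without 0 h replicate 2 and 137 without 4 h replicate 1, and the 20 h count 1486 without 0 h replicate 1, 1244 without 0 h replicate 2 and 2048 without 20 h replicate 2.

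As sets in iMEFs at 20 h, cell cycle, replication-dependent histones, integrated stress response, splicing factors, ribosome biogenesis and fibroblast markers ranked lower. Here 36, 48, 15, 16, 12 and 11 of 36, 58, 23, 41, 39 and 28 members were lower and 0, 1, 1, 0, 1 and 0 higher (36, 51, 16, 18, 15 and 17 and 0, 2, 1, 0, 1 and 0 adjusted over the list alone). The lists of p53 targets, small nucleolar RNA hosts, nuclear long noncoding RNAs, structured small RNAs and immediate-early genes ranked higher. Here 23, 5, 6, 4 and 2 of 30, 19, 18, 67 and 24 members were higher and 2, 2, 0, 3 and 0 lower (23, 5, 6, 3 and 1 and 2, 3, 0, 2 and 0 adjusted over the list alone). At 4 h cell cycle, integrated stress response, cytosolic ribosomal proteins and ribosome biogenesis ranked lower. Here 0, 0, 0 and 0 of 36, 23, 71 and 39 members were lower and 0, 0, 0 and 0 higher (0, 9, 0 and 0 and 0, 0, 0 and 0 adjusted over the list alone). Also at 4 h p53 targets, nuclear long noncoding RNAs, structured small RNAs, mitochondrial transcripts, small nucleolar RNA hosts and replication-dependent histones ranked higher. Here 1, 3, 1, 0, 3 and 2 of 30, 18, 67, 11, 19 and 58 members were higher and 0, 0, 1, 0, 0 and 0 lower (9, 3, 3, 0, 8 and 3 and 1, 0, 1, 0, 6 and 1 adjusted over the list alone). Hosts had a median of -0.14, a mean of 0.17 and a rescaled median of 0.02, and histones a median of -0.06 and a rescaled one of 0.10. None held (adjusted p = 0.914 at 4 h and 0.674 to 0.843 at 20 h with an estimated correlation). On rescaling camera calls of small nucleolar RNA hosts and structured small RNAs ended (adjusted p = 0.166 and 0.322). At 20 h rescaling ended that of structured small RNAs (adjusted p = 0.0849).

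**Figure D3:**
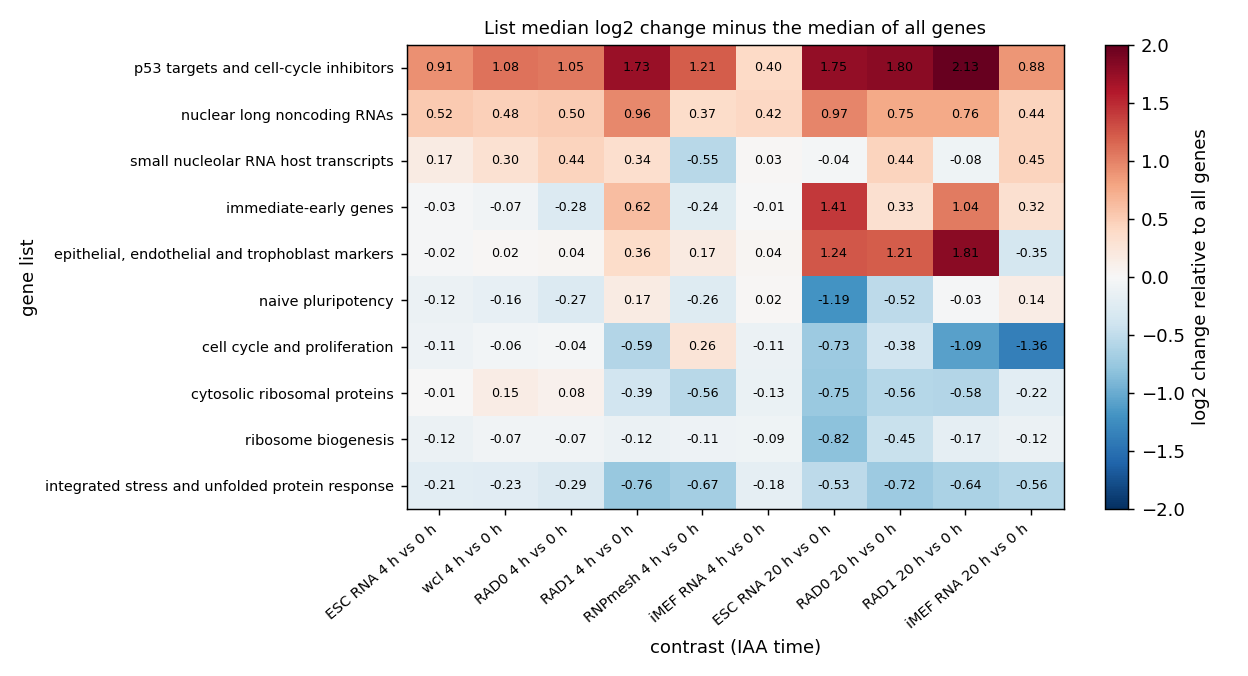
Heat map of the median log2 change of 10 gene lists (vertical axis) minus the median of all genes in 10 contrasts with IAA (horizontal axis), with the value in each cell and red above and blue below 0. The p53 list is above 0 in each, reaching 2.13 in RAD1 at 20 h.

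Changes were then compared between tables that share no library. Across genes, which are not independent replicates, the 4 h changes in ESC total RNA had a Spearman rho of 0.644 with wcl, 0.581 with RAD0, 0.455 with chrRNP, 0.363 with iMEFs, 0.283 with nascent RNA and 0.235 with RNPmesh. Among genes with a mean of at least 5 that with RNPmesh was 0.135. With 1 library per group at 4 h rho ranged from 0.488 to 0.555 for wcl, 0.445 to 0.485 for RAD0, 0.169 to 0.489 for chrRNP, 0.222 to 0.340 for iMEFs, 0.171 to 0.272 for nascent RNA and 0.118 to 0.314 for RNPmesh, so wcl and RAD0 lay above iMEFs, nascent RNA and RNPmesh, while chrRNP overlapped all of them and the order of those 3 is not settled. The 20 h changes in ESCs had a rho of 0.758 with RAD0 (0.703 to 0.724 with 1 library per group) and 0.567 with iMEFs (0.489 to 0.547). Of the 26 lists, fixed with the contrasts before the data were examined, the two-cell-stage genes had fewer than 5 measured members in every contrast and were not tested. Camera called 182 of 535 list results, of which 34 were also called with an estimated correlation.

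Sucrose gradients asked how nuclear RNA sediments after 12 h. There was 1 library per fraction and time, so no difference between groups was tested. For each of 3428 genes with summed values of at least 80 the mean fraction number was weighted by value. Its median over genes moved from 4.49 to 4.98, a median shift of 0.48, with 1487 genes up and 25 down by 0.5 or more. Values of each fraction are normalized within its own library, so these shifts also depend on library composition. Rpph1, the largest gene of F2, took 24.29% of its summed value at 0 h and 29.17% at 12 h. Setting libraries to equal totals does not remove this dependence. A shift shared by most genes therefore cannot be read as changed sedimentation. Tfpi, a coagulation inhibitor, shifted by 1.11 and Fubp1, a nucleic acid binding protein, by 1.04. Snhg9 shifted by -0.56, from 4.29 to 3.73, and Wsb1 by -0.42. Small nucleolar RNA hosts moved less than all genes, with a median shift of 0.09 over 16 members, lower than in all of 10000 random lists. Histones (0.32, 54 members) and structured small RNAs (0.26, 87 members) were also below all random lists, and p53 targets (0.36, 17 members) were at percentile 0.24. With fraction libraries set to equal totals the first 3 lists stayed below all random lists and p53 targets were at percentile 2.88. The random lists were matched on expression and not on position in the gradient. At 0 h the mean fraction of hosts, histones and structured small RNAs was at percentiles 99.6, 0 and 100. Whether their small shifts follow from that position was not tested. Mitochondrial transcripts were at percentile 98.5 (0.56, 13 members), which did not hold with equal totals (percentile 83.1, 0.49). Leaving out F2 and F9 gave 369 of 2784 genes shifted by 0.5 or more in place of 1512 of 3428.

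**Figure D4:**
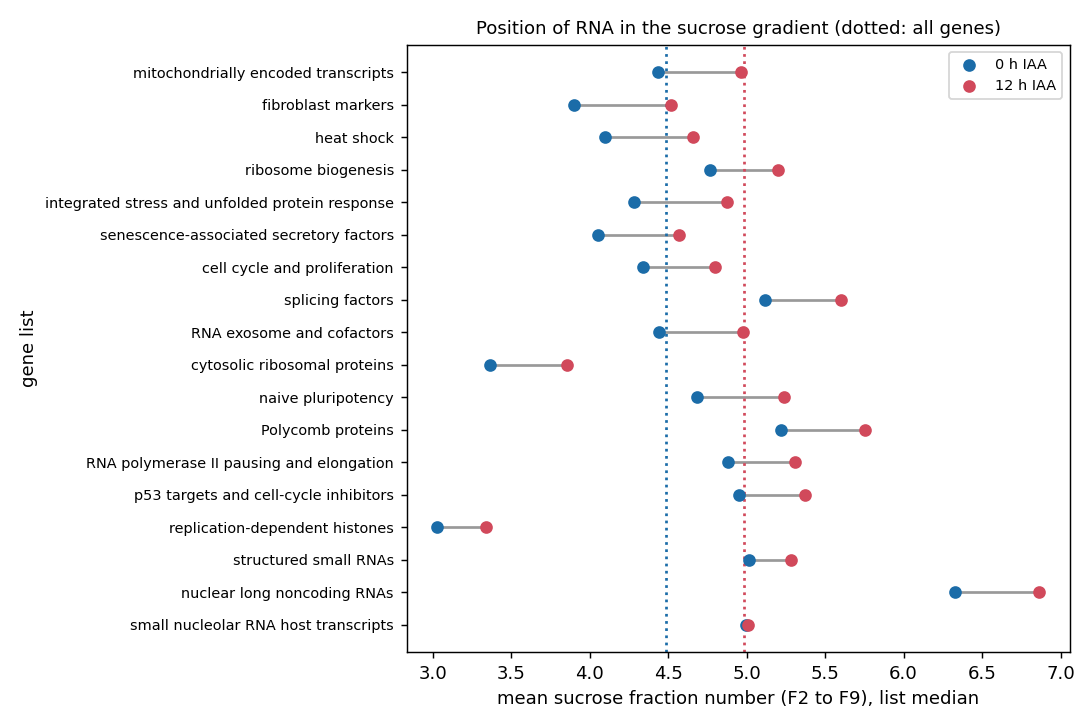
Median over list members of the mean sucrose fraction number (F2 to F9, horizontal axis) for each gene list (vertical axis), at 0 h (blue) and 12 h (red) of IAA from 1 library per fraction; dotted lines mark the medians of all genes, 4.49 and 4.98. Hosts went from 4.99 to 5.01, while cell cycle genes went from 4.34 to 4.8.

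H3K27ac, a mark of active promoters and enhancers, was compared as peak lists without scores, so no height was tested, and peak starts are printed as deposited. At 0 h 16239 peaks were listed and at 4 h 20449. Of the 0 h peaks 14247 (87.7%, exact 95% interval 87.2 to 88.2) overlapped a 4 h peak, and of the 4 h peaks 14160 (69.2%, 68.6 to 69.9) overlapped a 0 h peak. A 4 h peak (chromosome 13, 110394842 to 110395645) lay on the start of Plk2, whose nearest 0 h peak was 201939 bp away. At Btg2 the peak was 599 bp wide at 0 h and 2202 bp at 4 h, and Mdm2 had a peak over its start in both lists. Distances were taken to the nearer end of a gene, whichever its strand, so a near peak need not be at a promoter. At Id3 the nearest peak was 1881 bp away at 0 h and 20305 bp at 4 h, both from the gene end at 136145392. These genes are examples: of 199 genes the naming rule gave for ESCs, 145 had a peak within 2000 bp at 0 h and 145 at 4 h, 9 gaining and 9 losing one. Of 647 genes with a peak within 2000 bp in the 4 h list alone, 8.35% were called higher and 14.2% lower in ESC RNA at 4 h, with a median change of -0.24. The shares were 2.86% higher and 24.9% lower of 385 with a peak in the 0 h list alone, 5.10% higher and 24.8% lower of 7916 with a peak in both and 2.50% higher and 13.9% lower of 3513 with a peak in neither. The number of replicates behind each list, the threshold for a peak and which of 2 sets of 0 h libraries gave the 0 h list are not given in the sources used here.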

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

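In this part, the tests of library scaling, of nascent RNA, of IAA itself and of values near the floor were chosen only after the results were seen. The spread printed with a median is an approximate margin of error of that median, from the interquartile range over genes and their number. It treats genes as independent and leaves out variation between libraries, so the weighing below holds over genes only.

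The first pattern is that the median p53 target rose after IAA. Once each library was rescaled to its median gene, the list still rose by a median of 0.875 (log2; spread 0.361, 28 members), which argues against scaling of whole libraries as the whole cause. In nascent RNA at 4 h the list lay 1.513 above the median of all genes (spread 0.417, 24 members), which argues against slower decay with no more transcription. An effect of IAA itself cannot be told apart from loss of EXOSC2, since 0 libraries of IAA-treated cells without the degron were used. A candidate explanation left open is that loss of the exosome activates p53.

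The second pattern is the smaller response to retinoic acid with IAA, singled out because the response differed between IAA times in a direct test. At 20 h the retinoic acid list had a median interaction of -1.343 over 30 members. It was -1.279 after rescaling (spread 0.449) and at most -1.289 without any 1 of the 8 libraries (spread 0.465), which argues against scaling and against a single library. Among 27 members at 5 or more with retinoic acid and without IAA, the median change with IAA under retinoic acid was -1.809 (spread 0.461). That fall therefore did not start near the floor. For the interaction the floor is left open, since an equal fall could not show in members near it without retinoic acid. Without retinoic acid or IAA, Hoxb1, Hoxb5 and Hoxb6 stood at 0.329, 0.138 and 0.0965 FPKM, and Gbx2 at 95.25. Less transcription and faster loss of these transcripts may both contribute, and an effect of IAA itself was not tested for this list. Effects of retinoic acid and of lacking LIF cannot be told apart in RAD1 either.

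The third pattern is that 4 classes of long noncoding transcripts rose while coding ones fell in ESCs at 4 h. Small nucleolar RNAs did not rise (median -0.43). Antisense transcripts rose by a median of 0.886 after rescaling (spread 0.112, 157 transcripts), which argues against scaling for that part. Transcripts of these classes that overlap no coding locus rose by a median of 0.458 (spread 0.101, 303 transcripts), which argues against reads from overlapping coding genes for the classes pooled. For 1 class, processed transcripts, the 49 without overlap had a median of 0.082 (spread 0.163), and of 0.352 after rescaling. The answer there depends on the scaling, so such reads are left open. The camera call of that class ended with an estimated correlation (adjusted p = 0.058). The fall of coding transcripts cannot be told apart from scaling, since rescaling to the median gene itself sets their median near 0 (-0.067). In nascent RNA at 4 h the antisense, bidirectional, long intergenic and processed classes had medians of 0.11, 0.54, 0.07 and 0.06. Camera called none of them (adjusted p = 0.144, 0.144, 0.247 and 0.402). At 2 h it called the antisense, bidirectional and long intergenic ones (adjusted p = 0.0289, 0.0178 and 0.0322). Those calls ended with an estimated correlation (adjusted p = 0.0518, 0.0743 and 0.0518). Reduced degradation of long noncoding RNA after loss of the exosome is a candidate explanation for the rise, as a hypothesis. More transcription is left open too.

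Other results stood out because groups differed in a direct test. Between 4 and 20 h in ESCs 7034 genes differed, between the changes in chrRNP and cyto 19, and in the response to retinoic acid 3941 at 20 h and 4195 at 4 h. At 20 h the median interaction was -0.659 for cell cycle and 0.476 for immediate-early genes. At 4 h it was 0.673 for histones, 0.465 for naive pluripotency, 0.626 for p53 targets, -0.588 for cell cycle and 0.828 for immediate-early genes. The histone value covers polyadenylated RNA only.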

How the results depend on the processing

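In this part only limma-voom was chosen after the data were seen. Of 164 values of named genes, 161 kept their direction and their side of the threshold with a pseudocount of 0.1, 154 with no filter, 160 after rescaling, 158 with the replicate block and 161 without the trend. Leaving out 1 library kept 657 of 720. When a group is left with 1 library, that library is assumed to vary like the other groups. For the results given next, which did not hold, the cause was not tested.

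With no filter the number of genes called was 168 in ESCs at 4 h, 10, 33 and 79 in nascent RNA at 1, 2 and 4 h, 74 for chrRNP minus cyto, 1199 in RNPmesh at 4 h, and 99 and 2199 in iMEFs at 4 and 20 h. After rescaling it was 1096 in ESCs at 4 h, 1901 in chrRNP, 2859 in np, 1637 in wcl, 57 for chrRNP minus cyto, 1757 in RAD0 at 4 h and 332 in iMEFs at 4 h. With replicate number as a block it was 1170 in ESCs at 4 h, and 0 and 2 in nascent RNA at 1 and 4 h by limma, where the block also takes up degrees of freedom. In nascent RNA at 4 h it ended the calls of Plk2, Ccng1, Neurod1, mt-Co3, Lin28a and Tdgf1 (adjusted p = 0.0536, 0.083, 0.0754, 0.083, 0.083 and 0.0868), and of no other named gene. With a pseudocount of 0.1 it was 0 and 4 in nascent RNA at 1 and 2 h by limma, without the trend 16 at 2 h, and with limma-voom 77 and 640 at 2 and 4 h. Of 182 lists called by camera, 34 held with an estimated correlation.

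Leaving out 1 library gave 180 to 5114 called genes in ESCs at 4 h, 0 to 6, 0 to 4 and 3 to 7 in nascent RNA at 1, 2 and 4 h, 565 to 5550 in chrRNP, 2063 to 2187 in np, 470 to 607 in cyto and 1134 to 1246 in wcl. It gave 8 to 2690 for chrRNP minus cyto, 55 to 2750 in RNPmesh at 4 h, 1250 to 1727 in RAD0 at 4 h, and 129 to 163 and 1244 to 4844 in iMEFs at 4 and 20 h. Libraries that moved a count by more than 1.5 times are named in the results. The uncalled change of Exosc2 changed sign. It was -0.135 in chrRNP after rescaling, and leaving out 1 library gave -0.035 to 0.455 in nascent RNA at 4 h, -0.139 to 0.145 in chrRNP, -0.188 to 0.108 in cyto and -0.173 to 0.314 in RAD1 at 20 h.

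In the sucrose gradients 4473 of 11710 genes shifted by 0.5 or more with a minimum sum of 8, where more genes entered, and 369 of 2784 without the first and last fraction, against 1512 of 3428. The median shift was 0.4414 with a minimum sum of 8, 0.4432 with equal totals and 0.3606 without those fractions. With reciprocal overlap of 50% the shares of shared peaks were 78.87% and 62.63%, and with peaks within 1 kb merged 88.6% and 68.53%. Across genes with a mean of at least 5, rho with ESCs was 0.1352 for RNPmesh, 0.6076 for RAD0 and 0.3256 for iMEFs at 4 h, and 0.7926 for RAD0 at 20 h. With a pseudocount of 0.1 it was 0.621 for wcl and 0.5684 for RAD0 at 4 h. Scaling to spike-ins and using the higher-scoring peaks were not run, since the tables used here hold neither spike-in transcripts nor scores. The depth behind the FPKM values is not given in the sources used here.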

Other observations

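The grouping by annotated class was chosen only after the values were seen. In the sucrose gradients, with 1 library per fraction, 21 small nuclear RNAs had a median shift of -0.21 and 18 processed transcripts one of 0.05. The nuclear noncoding RNA Malat1 shifted by 0.57, the nucleolar protein gene Ncl by 0.85 and Dis3, a catalytic subunit of the exosome, by 0.84. Each is the largest shift of its list. The median shift was 0.25 over nuclear long noncoding RNAs (percentile 2.03 of random lists), 0.53 over ribosome biogenesis (percentile 94.1) and 0.48 over RNA exosome and cofactors (percentile 56.8), against 0.48 over all genes. With fraction libraries set to equal totals these percentiles were 14.2, 68.4 and 37.9, so the low rank of nuclear long noncoding RNAs did not hold.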
